A study of Mus musculus with 16 samples.

How the data were processed

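Cerebral cortex RNA from 16 male mice was measured on 1-colour Agilent mouse expression arrays, 1 array per mouse. Per the labels, the mice were Neil1 knockouts on a C57BL/6 background or wild-type littermates, 28 to 42 weeks old. Per the labels' protocols, they received whole-body gamma radiation (6 Gy, delivered at 0.74 Gy/min) or a sham exposure, and cortex was collected 20 h later from 4 mice in each of 4 groups. The same protocols state that BrdU, a thymidine analogue taken up by cells that copy their DNA, was injected at 100 mg/kg before the exposure and again 2 h after it. Cy3-labelled cRNA was made from total RNA, per the labels' protocols.

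Per the file headers, the authors scanned each array in 1 channel at 3 micron resolution and extracted it with Agilent Feature Extraction 12.0.3.1. The spot intensity used here is the processed signal of that program, which per the file headers was background-subtracted and detrended within the array and was not scaled between arrays. The deposited flags of the same files gave, for each spot, whether it was well above background, saturated or an outlier. The authors also deposited a table with a score for 42859 features of each array. How that table was made is not given in the sources used here. Its columns had mean 0, SD 1 and a median of -0.08, and each correlated with the log signal of its own array with r of 0.9996 or more, so it was read as z-scores of log signal and used as an alternative only. It held 40169 of the 56605 probes, among them all 32121 that were well above background on 16 arrays, and the rule by which the others were left out is not given in the sources used here.

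The log2 of the processed signal minus the 75th percentile of the same array was the expression value, so every level in the text is a log2 signal relative to that percentile. Control spots were left out, spots marked as nonuniform or as population outliers were set to missing, and spots of 1 probe were averaged. A probe was kept when it was well above background on at least 4 of the 16 arrays, which left 39589 of 56605 probes, and a gene needed a value on at least 12 arrays. Of the 35886 probes with a RefSeq accession, 32994 were named through a RefSeq gene table of the assembly GRCm38.p6. A further 7284 probes with an Ensembl transcript and 13435 other probes were left unnamed and out of the gene tests. A gene with several kept probes (6579 genes) was represented by the brightest, and the other probes were compared with it. The array design names an older assembly than the gene table, so the table served only for names and for which genes lie near each other.

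The 17436 genes were tested with limma 3.58.1 (R 4.3.3, with statmod 1.5.0) in 1 model with a mean per group over all 16 arrays, with 12 residual degrees of freedom and moderated variances. The 6 contrasts were irradiation in wild type, irradiation in knockout, their average, genotype in sham, genotype after irradiation, and the interaction. P-values were two-sided and adjusted by the Benjamini-Hochberg method within a contrast, and a gene was called at an adjusted p under 0.05. Gene lists with at least 5 tested members were compared with the other genes by limma's camera at a preset correlation of 0.01, adjusted over the 35 lists of a contrast. Each was tested again with the correlation estimated from the data, and 56 genes with a missing value were left out of the list tests. The lists covered cell types of the brain and blood, neighbouring brain regions, DNA repair, stress and immune pathways. Calls near Neil1 were compared with calls elsewhere by Fisher's exact test in a window of 20 Mb on each side, and the level of Neil1 by exact permutation tests.

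The groups, contrasts, tests, gene lists, naming rule and first set of alternatives were fixed before the data were examined. By that rule the text names Neil1, up to 10 genes with the largest called increase and 10 with the largest called decrease per contrast whose arrays did not overlap between groups, and up to 4 members of each list with the smallest p. The overlap condition was not applied to the average and interaction contrasts. Where fewer than 5 genes were called, the 10 with the smallest p are named. Some genes that the rule selects are not reported here. Genes named outside the rule are said to have been chosen after their values were seen. Where a gene was not well above background on any array of the dimmer group, its fold is given as a bound, "at least N-fold". The dim group was then represented, per array, by the higher of the dim probe's own signal and the lowest signal of any probe well above background.

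The alternatives fixed at the same time were normexp background correction, quantile and z-score normalization, no filter or a strict filter on dim probes, fits of 2 groups only, trended and robust variances, array weights, the replicate number as a block, other probe rules, a 1.5-fold minimum, the deposited scores, and leaving out each array in turn. Normexp (offset 50) was run on the median spot and background signals, because the mean spot signal is not among the columns of the files used here. Cyclic loess normalization, a striatal marker covariate, list tests with each array left out in turn and leaving out the 2 arrays with the fewest probes above background were alternatives chosen after seeing the data. Those 2 arrays, the 2 dimmest, were irradiated labelled knockout replicates 3 and 4, so 2 arrays of that group remained.

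The workflow was tested on simulated arrays with the means and spreads of the real genes. The noise was drawn independently for each gene and array, so correlation between genes and structure among arrays were not simulated. For irradiation in wild type over 17380 genes, 37.3% of 67 genes changed 1.5-fold, 65.7% of 67 genes changed 2-fold and 89.4% of 66 genes changed 4-fold were called, and 0 genes were called when nothing was changed. The adjustment is stricter when fewer genes change. These rates are therefore not the sensitivity of the real contrast, where 13 genes were called. In the run with changed genes, 3 unchanged genes were also called. A simulated shift of a gene list ranked 1 among the 35 lists. Because the simulated genes were independent, this does not test camera's preset correlation or the rate of false calls on real arrays.

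All wild-type arrays lay on slide 1 and all labelled knockout arrays on slide 2, so slide and genotype cannot be told apart. On both slides the sham arrays filled row 1 and the irradiated arrays row 2, so row and treatment cannot be told apart either. The replicate number equalled the slide column on 16 of 16 arrays, so a block for one is also a block for the other. No array repeated another: the correlation of log2 signal between arrays ran from 0.972 to 0.993. The precision of every value is limited by the number of arrays, 4 per group.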

Results

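The arrays compared the cerebral cortex of wild-type mice and of mice labelled Neil1 knockout, 20 h after 6 Gy of whole-body gamma radiation or a sham exposure, with 4 mice in each group. NEIL1 is a DNA glycosylase that removes oxidised bases in base excision repair, and the title of the series names neurogenesis and neuroinflammation after stress as its subject. The 75th percentile of processed intensity was 2415 ± 274 (SD, n = 4) in wild-type sham, 2301 ± 235 in irradiated wild type, 1778 ± 343 in labelled knockout sham and 1333 ± 301 in irradiated labelled knockout arrays. On average 70.8%, 67.3%, 67.6% and 65.5% of spots were well above background in these groups, and the share on single arrays ran from 62.4% to 72.4%.

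Neil1 itself was read first, in every array. Its probe gave -3.30, -3.75, -3.96 and -3.60 (log2 signal relative to the array's 75th percentile) in replicates 1 to 4 of wild-type sham, and -3.39, -3.61, -4.32 and -3.69 in irradiated wild type. It gave -2.17, -2.47, -2.60 and -2.27 in labelled knockout sham, and -2.19, -2.56, -2.15 and -2.55 in irradiated labelled knockout. The probe was thus brighter in the arrays labelled knockout, 2.42-fold in sham and 2.62-fold after irradiation, with no overlap between the arrays of the 2 genotypes in either comparison (exact permutation test, two-sided p = 0.0286 each, the smallest that 4 against 4 arrays allow). Irradiation left it within the spread between mice in wild type (log2 difference -0.10, exact p = 0.714) and in labelled knockout (0.02, exact p = 0.83). The labels do not say which part of the gene was deleted, and the position of the probe within the transcript is not given in the files used here, so this probe does not check the genotype labels. Directions between genotypes below therefore rest on the labels alone.

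In wild-type cortex, irradiation raised a set of p53 target genes and lowered a mitotic kinase and a microglial receptor. Gdf15, a stress-induced cytokine, rose from -6.18 ± 0.32 to -4.16 ± 0.09 (SD, n = 4), 4.05-fold. Cdkn1a, which encodes the cyclin-dependent kinase inhibitor p21, rose 2.68-fold (log2 change 1.42, with another kept probe at 4.51), and Mgmt, which removes alkyl groups from guanine in DNA, rose 2.62-fold from -2.30 ± 0.20 to -0.91 ± 0.16. Pbk, a mitotic kinase, was not well above background on any irradiated array and lay at least 1.66-fold lower than in sham. P2ry12, the purinergic receptor by which resting microglia sense nucleotides, fell by 0.62 ± 0.10 (SE) on the log2 scale.

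With limma and Benjamini-Hochberg adjustment, 13 of 17436 genes were called in wild type, 11 higher and 2 lower, and 344 (1.97%) had an unadjusted p under 0.05. Chance gives a share of 0.05, so the 344 are no evidence of further changed genes. Non-overlapping groups were found for 1.97% of genes, where chance gives 2.86%. Of 34 tested p53 target genes, 8 rose and 11 rose when adjusted over the list alone (camera adjusted p = 4.25e-32, and adjusted p = 0.000158 with an estimated correlation). Besides Gdf15 and Cdkn1a, these included Eda2r, a tumour necrosis factor receptor family member that was at least 6.72-fold higher because it was not well above background in sham. They also included Dcxr, a carbonyl reductase (log2 change 1.67 ± 0.20), Ephx1, the microsomal epoxide hydrolase (1.28 ± 0.13), Tnfrsf10b, a death receptor (1.18 ± 0.13), and Trp53inp1, a p53-induced regulator of autophagy (1.03 ± 0.09, with its other probe at 0.57). Rps27l, a ribosomal protein paralogue named after its values were seen, completed the group at 0.66 ± 0.10. Outside the list, Cox6b2, a cytochrome c oxidase subunit best known from testis, rose by 1.43 ± 0.19, and Alox5, the lipoxygenase of leukotriene synthesis, by 0.85 ± 0.13.

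Cell division genes were lower as a group in irradiated wild type (camera adjusted p = 5.48e-17, and adjusted p = 0.0041 with an estimated correlation), with 35 of 42 members lower. Of these members 1 fell, Pbk, and 12 fell and 1 rose when adjusted over the list alone. Oligodendrocyte precursor markers were also lower as a group (camera adjusted p = 0.000237, and adjusted p = 0.016 with an estimated correlation), with 16 of 21 lower and 0 of them called by limma, or 1 when adjusted over the list alone. Neu4, a sialidase of these cells, changed by -0.51 (limma adjusted p = 0.36) and Gpr17, a receptor of committed precursors, by -0.45. Markers of other cell types and regions were lower too, with 0 called by limma. Among them were those of mature oligodendrocytes (median -0.32, 20 of 20 lower), thalamus (-0.27, 10 of 14) and pericytes and smooth muscle (-0.19, 11 of 17) by camera (adjusted p = 0.000105, 0.0134 and 0.0164, but adjusted p = 0.553, 0.461 and 0.469 with an estimated correlation). Endothelial markers had a median of -0.18 (camera adjusted p = 0.0807). Without irradiated wild-type replicate 4 these 3 calls were lost (camera adjusted p = 0.246, 0.0781 and 0.126), and without irradiated replicate 2 those of thalamus and pericytes (0.0582 and 0.176). Without wild-type sham replicate 2 the thalamic median was 0.13 (camera adjusted p = 0.747) and the pericyte list had adjusted p = 0.0555, or 0.0656 without sham replicate 1. Lymphocyte markers were also called lower (median -0.03, 8 of 16 lower, camera adjusted p = 0.0102, but adjusted p = 0.126 with an estimated correlation). Hippocampal markers were called higher (median 0.16, 13 of 15, camera adjusted p = 0.0489, but adjusted p = 0.185 with an estimated correlation). Interferon-stimulated genes had a median of 0.18 with 27 of 36 members higher and 0 called (camera adjusted p = 1.06e-05, but adjusted p = 0.461 with an estimated correlation). Microglia markers had a median of -0.14 and 1 member that fell, P2ry12 (camera adjusted p = 1.87e-05, but adjusted p = 0.151 with an estimated correlation). In all, 17 of 35 lists were called at the preset correlation and 3 with an estimated correlation. The count of 13 genes rose to 21 with array weights, and the call of P2ry12 was lost in 23 alternatives and kept in 9.

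**Figure D1:**
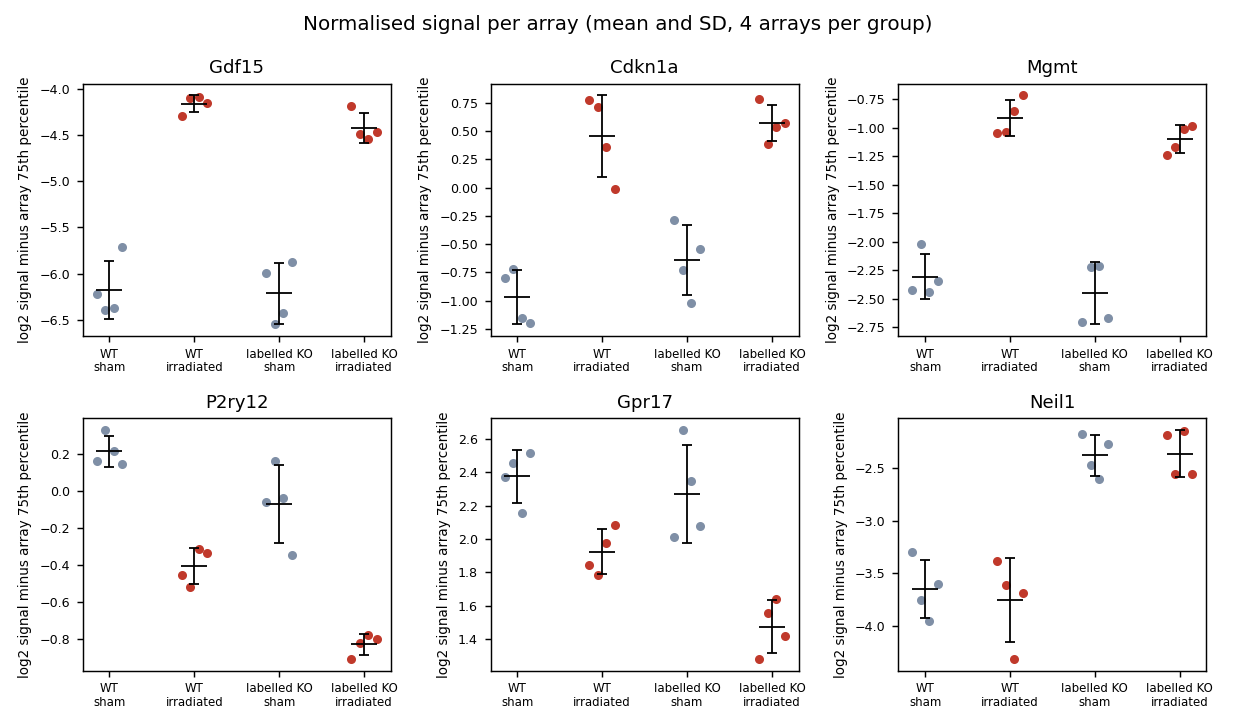
Log2 signal minus the array's 75th percentile for Gdf15, Cdkn1a, Mgmt, P2ry12, Gpr17 and Neil1. Points are single arrays (grey sham, red irradiated), and black bars give the mean and SD of 4 arrays per group. Gdf15, Cdkn1a and Mgmt sit higher and P2ry12 and Gpr17 lower in the irradiated arrays of both genotypes, while Neil1 is separated by genotype (2.42-fold in sham).

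In labelled knockout cortex, 8 of 34 p53 target genes rose, and Cenpf, Gpr17 and P2ry12 were among the genes that fell. Gdf15 rose 3.46-fold, from -6.21 ± 0.33 to -4.42 ± 0.16 (SD, n = 4), Cdkn1a 2.32-fold (log2 change 1.21, with its other probe at 3.93) and Mgmt 2.55-fold. Eda2r was at least 4.58-fold higher. Cenpf, a kinetochore protein, was not well above background on any irradiated array and lay at least 2.14-fold lower (its other probe changed by -0.48), and Gpr17 fell from 2.27 ± 0.29 to 1.47 ± 0.16. P2ry12 fell by 0.76 ± 0.10 (SE) on the log2 scale.

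Limma with Benjamini-Hochberg adjustment called 21 genes, 13 higher and 8 lower, and 808 (4.63%) had an unadjusted p under 0.05. That is no more than the share of 0.05 that chance gives. Groups did not overlap for 2.19% of genes, where chance gives 2.86%. Of the p53 target genes, 8 of 34 rose, and 10 when adjusted over the list alone (camera adjusted p = 5.52e-22, and adjusted p = 0.00103 with an estimated correlation). Dcxr rose by 1.75 ± 0.20, Ephx1 by 1.32 ± 0.13, Tnfrsf10b by 1.08 ± 0.13 and Trp53inp1 by 1.04 ± 0.09. Cox6b2 rose by 1.42 ± 0.19, Epha2, an ephrin receptor kinase, by 1.15 ± 0.21, and Gtse1, a cell-cycle protein that binds p53, by 2.29 ± 0.41, although Gtse1 was well above background on 1 of 4 sham arrays.

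Among 42 cell division genes in labelled knockout, 33 were lower, 2 fell (Cenpf and Pbk, the latter at least 1.12-fold lower), and 8 fell and 1 rose when adjusted over the list alone (camera adjusted p = 9.4e-09, and adjusted p = 0.0392 with an estimated correlation). Of 21 oligodendrocyte precursor markers, 2 fell, Gpr17 by 0.80 ± 0.14 and Neu4 by 0.69 ± 0.12 (-0.17 on its other probe), or 3 when adjusted over the list alone (camera adjusted p = 8.03e-06, and adjusted p = 0.00624 with an estimated correlation). Interferon-stimulated genes had a median of 0.33 with 35 of 36 members higher, 0 called by limma over all genes and 11 higher when adjusted over the list alone (camera adjusted p = 6.86e-19, but adjusted p = 0.0901 with an estimated correlation). Examples were Usp18, an interferon-induced protease, at 1.08 ± 0.23 and Oasl2, an antiviral oligoadenylate synthetase family member, at 0.90 ± 0.18. Microglia markers had a median of -0.21 and 1 member that fell, P2ry12 (camera adjusted p = 5.6e-06, but adjusted p = 0.144 with an estimated correlation). The other genes that fell were Gp9, a platelet glycoprotein, by 1.06 ± 0.19, Ccl24, an eosinophil-attracting chemokine, by 0.83 ± 0.13, and Tmem45a by 0.69 ± 0.11. Choroid plexus markers had a median of 0.48 with 12 of 15 higher and 0 called by limma, or 1 when adjusted over the list alone (camera adjusted p = 0.000338, but adjusted p = 0.319 with an estimated correlation). In all, 9 of 35 lists were called at the preset correlation and 3 with an estimated correlation. The count of 21 genes was 6 in the fit of these groups alone, 13 with the slide column as a block, 11, 13 and 13 without labelled knockout sham replicates 2, 3 and 4, and 7 without the 2 dimmest arrays (irradiated labelled knockout replicates 3 and 4), an alternative chosen after seeing the data. The calls of Gpr17, Neu4, Gtse1, Gp9 and Epha2 were lost in 23, 25, 24, 23 and 20 alternatives and kept in 9, 7, 7, 9 and 12.

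Averaged over genotypes, irradiation changed 53 genes, 29 higher and 24 lower, by limma with Benjamini-Hochberg adjustment, of which 42 changed at least 1.5-fold. An unadjusted p under 0.05 was found for 871 genes (4.995%), no more than the share of 0.05 that chance gives. Of 34 p53 target genes 9 rose, of 42 cell division genes 7 fell and 1 rose, and Il7r, Cd79b, Gp9, P2ry12, Ctss, Gpr17 and Neu4 were among the other genes that fell. Gdf15 (1.90 ± 0.12, SE) and Dcxr (1.71 ± 0.14) rose, as did Eda2r (limma adjusted p = 3.26e-07) and Gtse1 (adjusted p = 0.00154). Pbk, Ccnb1, the cyclin of mitotic entry, and Pimreg, a mitotic regulator, fell (limma adjusted p = 2.91e-05, 0.00657 and 0.0227). Eda2r was not well above background on any sham array, nor were Pbk, Ccnb1 and Pimreg on any irradiated array. Gtse1 was well above background on 0 of 4 wild-type and 1 of 4 labelled knockout sham arrays. No size is therefore given for the averaged change of these 5 genes.

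Of 34 p53 target genes, 9 rose in the average and 14 when adjusted over the list alone (camera adjusted p = 1.75e-31, and adjusted p = 0.000174 with an estimated correlation), with 29 of 34 higher. The 9 were Eda2r, Gdf15, Dcxr, Cdkn1a (1.32 ± 0.13), Ephx1 (1.30 ± 0.09), Tnfrsf10b (1.13 ± 0.09), Trp53inp1 (1.03 ± 0.06) and, named after their values were seen, Rps27l (0.62 ± 0.07) and Aen, an apoptosis-enhancing nuclease (0.72 ± 0.10). Cdkn1a has another kept probe, which showed a larger change in the same direction (4.22). Mgmt (1.37 ± 0.10), Cox6b2 (1.42 ± 0.14) and Avil, an actin-binding protein (1.62 ± 0.22, and 0.86 on its other probe), rose outside the list.

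Of 42 cell division genes, 38 were lower, and 7 fell and 1 rose (12 and 1 when adjusted over the list alone, camera adjusted p = 7.3e-17, and adjusted p = 0.00296 with an estimated correlation). Those that fell were Pbk, Ccnb1, Cenpf (limma adjusted p = 0.000391), Ube2c, the ubiquitin-conjugating enzyme of the anaphase-promoting complex (-1.53 ± 0.30), Nusap1, a spindle protein (-0.94 ± 0.15), both measured above background on 1 of 4 irradiated arrays in each genotype, and, named after their values were seen, Prc1 (-0.66 ± 0.12) and Cdca3 (-0.65 ± 0.12). Cenpf was well above background on 3 of 4 wild-type and 0 of 4 labelled knockout irradiated arrays, and its other probe changed by -0.64. Spc25, a kinetochore protein, rose by 0.90 ± 0.13 on the brighter of its 2 kept probes, and the other is not reported here. Neural progenitor and neuroblast markers, the list closest to the neurogenesis of the series title, had a median of -0.07 with 0 of 25 called by limma (camera adjusted p = 0.316, and adjusted p = 0.742 with an estimated correlation).

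Oligodendrocyte precursor markers fell as a group, with 19 of 21 lower and 2 that fell, Neu4 (-0.60 ± 0.08, and -0.20 on its other probe) and Gpr17 (-0.63 ± 0.10), or 3 when adjusted over the list alone (camera adjusted p = 4.12e-07, and adjusted p = 0.00244 with an estimated correlation). Mature oligodendrocyte markers had a median of 0.01, with 10 of 20 higher, a mean of -0.07 and a test in the lower direction (camera adjusted p = 0.477). Among 24 microglia markers, P2ry12 (-0.69 ± 0.07) and Ctss, the lysosomal protease cathepsin S (-0.43 ± 0.08), fell, and 18 were lower (camera adjusted p = 1.03e-07, but adjusted p = 0.0825 with an estimated correlation). Adjusted over the list alone, 4 fell and 1 rose. Il7r, a cytokine receptor of lymphocytes (-0.98 ± 0.13), and Cd79b, a chain of the B-cell receptor (-0.74 ± 0.11), fell among 16 lymphocyte markers, and both were also the only members called when adjusted over the list alone. The lymphocyte list as a whole had a median of 0.05 and a mean of -0.07 (camera adjusted p = 0.316 in the lower direction). Outside the lists, Tnfrsf17, a receptor of plasma cells (-0.86 ± 0.13), and Gp9 (-0.90 ± 0.13) fell.

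Complement genes were higher as a group (camera adjusted p = 0.0011, and adjusted p = 0.033 with an estimated correlation), although their median change was only 0.06. Of 19 members 13 were higher, and 1 rose, complement factor B (Cfb, 0.88 ± 0.17), or 4 when adjusted over the list alone. Interferon-stimulated genes had 34 of 36 members higher and a median of 0.23, with 1 that rose, Oasl2 (0.68 ± 0.13), and 10 when adjusted over the list alone (camera adjusted p = 1.46e-17, but adjusted p = 0.0935 with an estimated correlation). Bst2, an interferon-induced membrane protein that tethers viruses, changed by 0.47 ± 0.09 (limma adjusted p = 0.0503). NF-kB and inflammatory genes, the list closest to the neuroinflammation of the title, had 0 of 27 called by limma and 5 higher when adjusted over the list alone (camera adjusted p = 0.0308, but adjusted p = 0.106 with an estimated correlation and 0.089 with the slide column as a block). Its camera call was also lost without any 1 of 5 arrays, wild-type sham replicate 1, irradiated wild-type replicate 3, labelled knockout sham replicates 2 and 3 and irradiated labelled knockout replicate 1 (adjusted p = 0.0802, 0.077, 0.0756, 0.15 and 0.0708). Glucocorticoid-induced genes had 2 of 25 that rose, Sult1a1, a sulfotransferase (0.69 ± 0.10 on the brighter of 2 kept probes), and Cdkn1a, which the p53 list also holds, and 5 when adjusted over the list alone (camera adjusted p = 2.48e-07, but adjusted p = 0.0555 with an estimated correlation). Base excision repair genes had a median of 0.02 and 0 of 23 called by limma (camera adjusted p = 0.827), and genes of the double-strand break response a median of 0.02 and 0 of 28 called (camera adjusted p = 0.715). The calls of Cfb, Oasl2, Ctss, Ube2c, Prc1 and Cdca3 were lost in 22, 20, 20, 25, 15 and 21 alternatives and kept in 8, 11, 11, 5, 16 and 10. The count of 53 genes became 84 with array weights, and striatal marker scores, which differ with how a cortex is dissected, ranged from -2.30 to 1.52 between arrays (log2) with group means of -0.002, -0.26, -0.10 and -0.35.

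**Figure D2:**
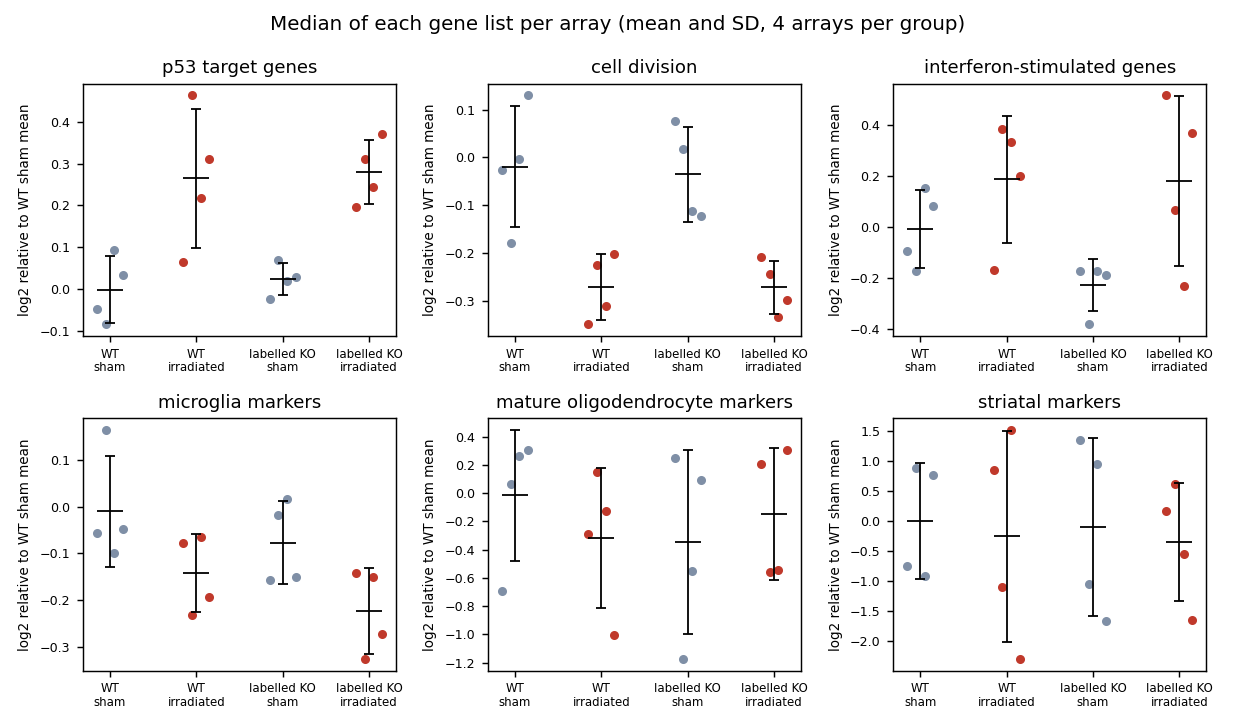
Median log2 signal of 6 gene lists per array, relative to the wild-type sham mean, by group. Points are single arrays (grey sham, red irradiated), and black bars give the mean and SD of 4 arrays per group. The cell division list is lower on each irradiated array than on the sham arrays of its genotype, and the p53 list is higher in the same way in labelled knockout but overlaps in wild type (0.07 on irradiated replicate 1 and 0.09 on sham replicate 3), while the striatal list ranges from -2.30 to 1.52 without following the groups.

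Whether irradiation acted differently in the 2 genotypes was tested by the interaction, and no gene was called. The 9 p53 targets that rose in the average, Eda2r at background in sham among them, had a mean change of 1.44 in wild type and 1.42 in labelled knockout, a difference of -0.03 (95% interval -0.20 to 0.15). Over all 34 tested p53 targets, a list not selected by its change, the difference was 0.03 (95% interval -0.18 to 0.24). All 13 genes called in wild type (Eda2r, Gdf15, Pbk and P2ry12 among them) were also called in labelled knockout in the same direction, 11 higher and 2 lower, where independent lists would share 0.0082 and 0.000918. These lists are not fully independent, however, since both contrasts use the same variance estimate of each gene. Sham and irradiated arrays also lay in different rows of both slides, so an effect of the row would be shared as well. The 21 genes called in either genotype all changed in the same direction in both, and 2 of them had an unadjusted interaction p under 0.05. Of these, Ccl24 was chosen by the rule among the smallest interaction p-values, with -0.83 ± 0.13 in labelled knockout against -0.15 ± 0.13 in wild type (limma interaction, unadjusted p = 0.00253 and adjusted p = 0.9999).

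Limma called 0 of 17436 genes in the interaction, with 222 genes at an unadjusted p under 0.05 (1.27%), and 0 in each alternative fit, with 733 at an unadjusted p under 0.05 with array weights and 754 when every probe was tested. Since chance gives a share of 0.05, the p-values of the main fit were on the conservative side. The 0 calls therefore do not show that the 2 genotypes responded equally. The smallest p belonged to Smgc (0.72 ± 0.16), Tg, which encodes thyroglobulin (2.12 ± 0.51), Cabp4, a calcium-binding protein (1.44 ± 0.35), Olfr1383, an odorant receptor (1.43 ± 0.35), Pik3ap1 (1.04 ± 0.26), Ppp4r1l-ps (0.54 ± 0.14), Ankrd61 (0.90 ± 0.24), Speer4a (1.65 ± 0.44), Epb41l4b (1.01 ± 0.28) and Ccl24 (-0.68 ± 0.19). Each had a limma adjusted p of 0.9999, and Tg, Cabp4 and Speer4a were not well above background on any array of at least 1 group. Camera called 4 of 35 lists at the preset correlation and 0 with an estimated correlation. These were mature oligodendrocyte markers (median difference 0.50, 20 of 20 higher), interferon-stimulated genes (0.22, 35 of 36), endothelial markers (0.15, 21 of 22) and thalamic markers (0.34, 10 of 14), each with adjusted p = 0.772 with an estimated correlation. Without wild-type sham replicate 2 the thalamic difference was 0.01 (camera adjusted p = 0.861). Its call was lost without 8 of the 16 arrays, and with the slide column as a block its adjusted p was 0.0573. The endothelial call was lost without 5 arrays, with the lowest median of 0.06 without irradiated labelled knockout replicate 1 (camera adjusted p = 0.454). The interferon call was lost without that array as well (median 0.14, camera adjusted p = 0.0788), and the mature oligodendrocyte call without labelled knockout sham replicate 2 (0.26, camera adjusted p = 0.0593). The 95% intervals of the mean difference were -0.57 to 1.56 for mature oligodendrocyte markers and -0.24 to 0.75 for interferon-stimulated genes. Neural progenitor and neuroblast markers had a median difference of -0.09 (camera adjusted p = 0.398) and NF-kB and inflammatory genes of -0.05 (camera adjusted p = 0.726).

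The agreement of irradiation effects between genotypes was also measured across all genes, which are not independent replicates. The irradiation changes of the 2 genotypes correlated with r = 0.195 and rho = 0.170, with a jackknife SE of 0.348 for r over arrays. The value was -0.02 without the 2 dimmest arrays (irradiated labelled knockout replicates 3 and 4), an alternative chosen after seeing the data, and 0.0152, 0.0237, 0.0736 and 0.0802 without labelled knockout sham replicate 4, irradiated labelled knockout replicate 3, wild-type sham replicate 2 and irradiated wild-type replicate 2. It was 0.296 without labelled knockout sham replicate 3.

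**Figure D3:**
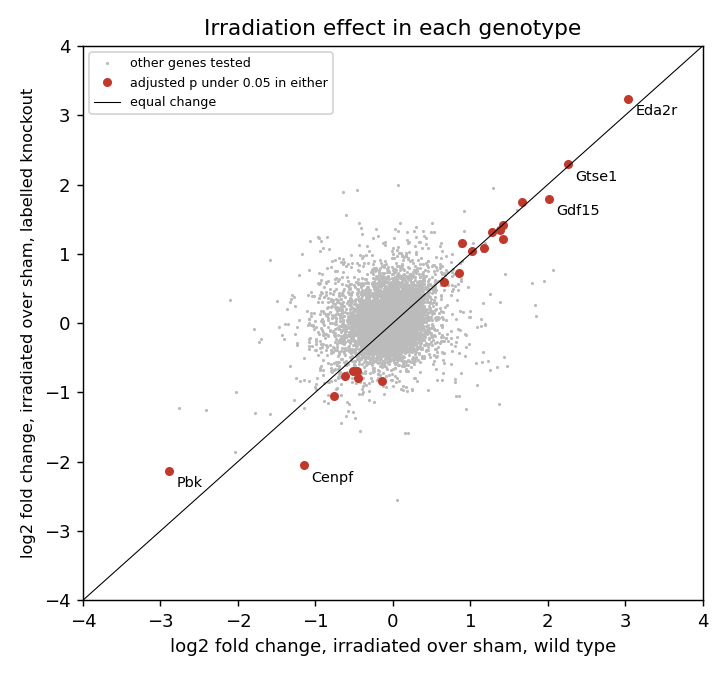
Log2 fold change of irradiated over sham in wild type (horizontal) against labelled knockout (vertical) for all 17436 genes tested. Red points are the 21 genes called in either genotype, which all lie in the quadrants of equal sign, and the line marks equal change.

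Between genotypes in sham cortex, 9 genes differed, and all 9 lie on the chromosome of Neil1. Nrg4, a neuregulin growth factor, was not well above background in labelled knockout sham and lay at least 2.75-fold lower than in wild type. Cd276, an immune checkpoint molecule, fell from -1.46 ± 0.26 to -3.60 ± 0.11 (SD, n = 4), 4.38-fold between wild type and labelled knockout, and Bco2, a carotenoid-cleaving oxygenase, differed 3.16-fold in the same direction. Atm, the kinase that signals DNA double-strand breaks, was 2.51-fold lower in labelled knockout (-1.96 ± 0.23 against -3.29 ± 0.22), and Neil1 was 2.42-fold higher.

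The other genes called by limma with Benjamini-Hochberg adjustment were Rpp25, a subunit of ribonuclease P (-1.45 ± 0.19, SE), Nxpe4 (-0.73 ± 0.11), Commd4 (-0.70 ± 0.09) and Ppcdc, an enzyme of coenzyme A synthesis, which was higher (0.66 ± 0.10). In total 2 were higher and 7 lower, 1340 genes had an unadjusted p under 0.05, and 4.82% of genes had groups that did not overlap, where chance gives 2.86%. Of 379 tested genes within 20 Mb of Neil1, 8 were called, against 0 of 17056 elsewhere (Fisher's exact p = 4.64e-14, two-sided, Neil1 left out), and all 8 were within 10 Mb in the gene order of GRCm38.p6. Atm and Commd4 have another kept probe each, which changed in the same direction (-1.02 and -0.69), and Nrg4 has 2 (-2.43 and -1.86).

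Of the fixed lists, base excision repair genes other than Neil1 had a median of 0.02 and 0 of 23 called in sham (camera adjusted p = 0.828), with Ung, the uracil glycosylase, at 0.64 ± 0.23 and Mpg, an alkylbase glycosylase, at -0.27 ± 0.12 on its brightest probe and 0.16 on another. Atm was the 1 member of 28 genes of the double-strand break response that fell (camera adjusted p = 0.165), and also the only one when adjusted over the list alone. Interferon-stimulated genes had a median of -0.24 with 35 of 36 members lower, 0 called by limma (camera adjusted p = 5.2e-05, but adjusted p = 0.811 with an estimated correlation). Thalamic markers (median -0.50), mature oligodendrocyte markers (-0.31) and excitatory neuron markers (0.25) were also called at the preset correlation and none with an estimated correlation (adjusted p = 0.811, 0.906 and 0.811 with an estimated correlation). With the slide column as a block, camera gave these 3 lists adjusted p = 0.0597, 0.114 and 0.0597. Wild-type sham replicate 2 stood at 0.79 for thalamic markers (others -0.36 to -0.13) and at -0.33 for excitatory neuron markers (others 0.12 to 0.18). Without it the medians were -0.21, -0.28 and 0.05 (camera adjusted p = 0.663, 0.164 and 0.417). Without labelled knockout sham replicate 2 the mature oligodendrocyte median was -0.08 (camera adjusted p = 0.964), and without labelled knockout sham replicate 1 the excitatory median was 0.15 (camera adjusted p = 0.185). Over the 16 arrays left out in turn, the calls were lost 4, 10 and 7 times. P53 target genes had a median of -0.005, although their test pointed higher (camera adjusted p = 0.852). The count of 9 genes was 2 in the fit of these groups alone, 18 with every probe tested, 45 with array weights, and 5 and 14 without labelled knockout sham replicates 3 and 2. The call of Neil1 was lost in 8 alternatives and kept in 24, and slide and genotype cannot be told apart in this comparison.

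**Figure D4:**
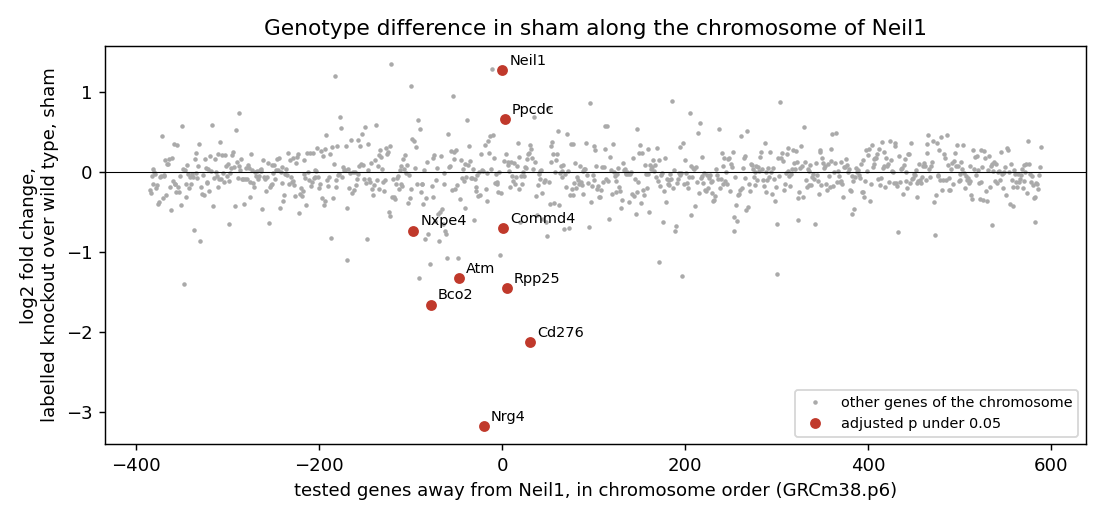
Log2 fold change of labelled knockout over wild type in sham (vertical) for tested genes on the chromosome of Neil1, placed by their order in GRCm38.p6 relative to Neil1 (horizontal). Red points are the 9 called genes, and grey points are the other tested genes of the chromosome.

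After irradiation, the genes around Neil1 differed between genotypes again, and a much wider set of genes was called. Cd276 was 5.04-fold lower in labelled knockout (-1.54 ± 0.29 against -3.88 ± 0.46, SD, n = 4), Bco2 3.19-fold, Atm 2.28-fold and Nrg4 at least 2.60-fold, while Neil1 was 2.62-fold higher. All 9 genes called in sham were called again in the same direction. Away from Neil1, the genes with the largest increases included Rn28s1, a large-subunit ribosomal RNA (5.23-fold, 4.60 ± 0.34 against 6.99 ± 0.43), and Cd247, the zeta chain of the T-cell receptor (4.59-fold). Neither was called in sham, but both were already higher there in labelled knockout. Rn28s1 ran from 3.17 to 4.945 in wild-type sham and from 4.948 to 6.49 in labelled knockout sham, and Cd247 from -2.83 to -1.19 and from -0.86 to 0.29. Both probes ranked the arrays in the same order in wild-type sham and in both labelled knockout groups, but not in irradiated wild type. Why the Cd247 probe followed that of a ribosomal RNA was not tested. Lymphocyte markers had a median of 0.07 in this comparison, with 0 of 16 called by limma (camera adjusted p = 0.865).

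Limma with Benjamini-Hochberg adjustment called 205 genes, 143 higher and 62 lower in labelled knockout, with 2901 at an unadjusted p under 0.05 and 8.74% of genes with groups that did not overlap, where chance gives 2.86%. Near Neil1, 20 of 379 genes were called, against 184 of 17056 elsewhere (Fisher's exact p = 2.14e-08). Lower genes of this neighbourhood were Rpp25 (-1.41 ± 0.19, SE), Pts, an enzyme of tetrahydrobiopterin synthesis (-1.38 ± 0.21), Man2c1os, an antisense RNA (-1.17 ± 0.19), Alg9, a mannosyltransferase of protein glycosylation (-0.90 ± 0.17), and, named after their values were seen, Commd4 (-0.65 ± 0.09) and Nxpe4 (-0.59 ± 0.11). Ppcdc, chosen in the same way, was higher (0.73 ± 0.10). Elsewhere in the genome Aspn, an extracellular matrix protein, lay at least 1.52-fold lower, but was higher with normexp correction (log2 change 0.38), and Ttc26, a ciliary transport protein, was at -0.95 on its brightest probe and 0.86 on another, so its probes disagree.

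Several of the largest increases were in genes not well above background on any irradiated wild-type array. These were Olfr836 and Olfr62, odorant receptors (at least 1.89- and 1.91-fold), Krt7, a keratin (at least 2.23-fold), Epsti1, an interferon-responsive gene (at least 1.88-fold), Il12b, a cytokine subunit (at least 1.76-fold), Tg (at least 1.74-fold) and Hoxc10, a homeobox factor (at least 1.42-fold). Olfr836, Epsti1 and Hoxc10 were measured above background on 2 of 4 irradiated labelled knockout arrays, and Il12b and Tg on 3. The mean 75th percentile used for scaling was 2301 in irradiated wild-type and 1333 in irradiated labelled knockout arrays. A signal near background therefore lies higher on the relative scale in labelled knockout, so these bounds cannot be told apart from an effect of scaling. Gjd3, a connexin, was higher by 1.94 ± 0.41. Among abundant transcripts, and named after their values were seen, Actb (0.43 ± 0.10), Eef1a1 (0.43 ± 0.09) and Ppia (0.55 ± 0.10) were called higher, as was the small nuclear RNA Rn7sk (1.23 ± 0.25), although Actb was at -0.003 after quantile normalization and -0.03 with the deposited scores.

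No list was called by camera after irradiation. Among 20 astrocyte markers, Slc1a2, the glutamate transporter (0.58 ± 0.13), and Clu, clusterin (0.40 ± 0.09), were called higher, or 3 when adjusted over the list alone (camera adjusted p = 0.187). Insig1, a sterol sensor (0.63 ± 0.12), was called higher and Lss, lanosterol synthase (-0.53 ± 0.12, with its other probes at -0.12 to 0.10), lower among 21 cholesterol synthesis genes (camera adjusted p = 0.962), where 2 were higher and 1 lower when adjusted over the list alone. Atp5b, a subunit of ATP synthase, was called higher (0.43 ± 0.09 on the brightest of 3 kept probes) among 29 mitochondrial respiratory chain genes, or 2 when adjusted over the list alone (camera adjusted p = 0.516). Base excision repair genes had 0 of 23 called by limma (camera adjusted p = 0.962), with Ung at 0.76 ± 0.23 and Xrcc1, a scaffold of this pathway, at -0.34 ± 0.10. P53 target genes had a median of -0.04 and a mean of 0.03, and neural progenitor and neuroblast markers a median of -0.06 and a mean of -0.007, while both tests pointed higher (camera adjusted p = 0.962 each). NF-kB and inflammatory genes had a median of -0.05 (camera adjusted p = 0.962). The calls of Slc1a2, Clu, Lss and Atp5b were lost in 20, 20, 20 and 16 alternatives and kept in 12, 12, 12 and 16. Those of Tg, Krt7, Hoxc10 and Actb were lost in 20, 17, 17 and 18 and kept in 11, 14, 14 and 12. The brightest probes of Cenpf, Col6a3, Neu4, Parp14 and Txnip, named as members of lists, were lower and another probe of each was higher, so these probes disagree.

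The count of 205 genes moved with most settings: it was 4 without the 2 dimmest arrays, an alternative chosen after seeing the data, 18 in the fit of these groups alone, 89 (37 higher and 52 lower) after quantile normalization, 443 (208 and 235) after z-scoring and 3382 after normexp correction. The 2 dimmest arrays were irradiated labelled knockout replicates 3 and 4. Leaving them out kept only 2 arrays of that group, so dimness and fewer arrays cannot be told apart there. It was 469, 31, 17 and 63 without irradiated wild-type replicates 1, 2, 3 and 4, and 110, 32, 37 and 30 without irradiated labelled knockout replicates 1, 2, 3 and 4. The genotype changes in sham and after irradiation correlated across genes with r = 0.564 and rho = 0.589, and 200 of the 205 called genes had the same sign in sham. Of the 205, 152 also had an unadjusted limma p under 0.05 in sham in the same direction.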

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

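Cyclic loess normalization and list tests with single arrays left out were tests chosen only after the data were seen.

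When limma tested all 39589 kept probes separately, 1839 were called between genotypes after irradiation, among them 569 of 13732 probes without a gene name. Probes without a name numbered 8 among the calls in sham, 2 for irradiation in wild type, 2 in labelled knockout and 8 in the average. That fit was adjusted over probes, so these counts cannot be set beside those of the gene tests. The wide set of genotype calls after irradiation is the pattern with the most technical explanations open. A gap in brightness between the slides could account for part of it: farther than 20 Mb from Neil1, 184 genes were called and 127 after cyclic loess normalization, of which 101 were shared, but that number ran from 9 to 362 as single arrays were left out, so the test does not settle it. A fixed difference between slides cannot be told apart from genotype, since the changes in sham and after irradiation correlated with r = 0.5635 across genes and either would give this. Signal specific to single probes also stays open, because other probes of 63 called genes changed by a median of 0.4391 of the reported change (95% interval 0.234 to 0.618) and 19 went the other way, while for 14 genes called for irradiation the median was 0.925 (0.402 to 1.34), an interval that overlaps the first. An effect of the genotype itself remains possible and could not be tested apart from the slide.

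Other splits of the arrays were tried for each count. In 1 of 35 splits, the real one, as many genes were called as the 13 for irradiation in wild type (highest other 2), the 21 in labelled knockout (highest other 1), the 9 between genotypes in sham (highest other 1) and the 205 after irradiation (highest other 6). This argues against chance alone for these counts but cannot exclude it. The smallest share that can be reached is 1 of 35, and it was not adjusted for the number of contrasts. For the average, 2 of 100 splits gave at least the real 53, the real one included, and the other gave 544, which points to a structure of the samples that was not identified. That split parted slide columns 1 and 2 from 3 and 4 in wild type but not in labelled knockout, and with the slide column as a block the average called 49 genes, 43 of them among the 53. From column 1 to column 4 the median local background fell from 39 to 30 in wild-type sham and from 38 to 30 in irradiated wild type. In labelled knockout it fell from 43 to 32 in sham and from 41 to 32 after irradiation. Whether this gradient gave the 544 calls was not tested. For the interaction, 100 of 100 splits gave at least its 0 genes (highest other 2), and since any split reaches a count of 0, this test decides nothing.

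Single arrays stood apart from the other 3 of their group in 8 of 316 groups of values tested, where chance gives about 15.8. Cabp4 was at -6.184 on labelled knockout sham replicate 4, with the others at -7.255 to -7.195. Ccnb1 was at -8.588 on irradiated wild-type replicate 4 (others -7.52 to -7.424), and Cenpf at -7.998 on irradiated labelled knockout replicate 4 (others -7.037 to -6.992). Il7r was at -5.265 on irradiated labelled knockout replicate 2 (others -5.794 to -5.714), and Lss at 0.2405 on labelled knockout sham replicate 2 (others -0.1963 to -0.1735). Tg was at -6.047 on wild-type sham replicate 4 (others -7.05 to -6.89), and Tmem45a at -3.856 on labelled knockout sham replicate 4 (others -3.635 to -3.611). The median of the interferon-stimulated genes was -0.3835 on labelled knockout sham replicate 2 (others -0.1889 to -0.1737).

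The effect of irradiation differed between genotypes by camera's interaction test at the preset correlation for mature oligodendrocyte markers (median difference 0.5007), interferon-stimulated genes (0.2202), endothelial markers (0.1488) and thalamic markers (0.3419), each with adjusted p = 0.772 with an estimated correlation. The thalamic difference was 0.01 without wild-type sham replicate 2 (camera adjusted p = 0.861).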

How the results depend on the processing

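Cyclic loess normalization, the striatal marker covariate, list tests with single arrays left out and leaving out the 2 dimmest arrays (irradiated labelled knockout replicates 3 and 4) were tests chosen after seeing the data. Over the 127 results for named genes, 1606 values kept direction and side of the threshold under other settings, 330 lost the call and 11 reversed, and with single arrays left out these numbers were 1594, 428 and 10. The cause was not tested except where fewer genes or arrays explain it. Whether low signal over background explains the changed calls of dim genes was not tested either. The median of all genes moved by under 0.1 (log2) in each setting.

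For irradiation in wild type the count was 21 with array weights. In labelled knockout it was 6 in the 2-group fit, 7 without the 2 dimmest arrays and 11 to 22 with single arrays left out, and in the average 84 with array weights. Between genotypes in sham it was 2 in the 2-group fit, 45 with array weights, 18 with all probes tested and 5 to 14 with single arrays left out. After irradiation it was 3382 with normexp, 89 with quantile normalization, 443 with z-scores, 1798 without the dim filter, 18 in the 2-group fit, 434 with array weights, 494 with the mean over probes, 1839 with all probes, 131 with the 1.5-fold minimum, 81 with the deposited scores, 4 without the 2 dimmest arrays and 17 to 469 with single arrays left out. Array names and their values stand with each comparison.

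The share of higher calls moved with scaling. In wild type it was 84.6%, and 100% with normexp and with the deposited scores. In labelled knockout it was 61.9%, 90% with normexp and 80% with the deposited scores. In the average it was 54.7%, and 82.5%, 65.8% and 69.4% with normexp, quantile and deposited values. In sham it was 22.2%, 45.5% with normexp and 33.3% with quantile normalization. After irradiation it was 69.8%, and 83.5%, 41.6%, 47.0%, 51.9% and 44.9% with normexp, quantile, z-score, deposited and cyclic loess values.

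With the replicate number, which equals the slide column, as a block (replicate block), 10, 13, 49, 11, 289 and 0 genes were called in the 6 contrasts in the order above. Same-numbered arrays correlated from -0.599 to 0.525 in their deviations and 5 of 16 arrays correlated best with their own number, so the numbers were not read as pairs. Of the 21 genes in labelled knockout, 11 remained among the 13. By camera with this block, hippocampal markers in wild type (adjusted p = 0.0797), neutrophil and monocyte markers in labelled knockout (0.126) and thalamic markers in the interaction (0.0573) were no longer called, and mitochondrial genes in labelled knockout (0.0363) and cholesterol genes in the average (0.0171) were, neither of them with an estimated correlation (adjusted p = 0.935 and 0.742, without the block). Gene list tests called 46 in all contrasts together, 10 with an estimated correlation, 35 to 58 with single arrays left out, 11 by fry in 1 direction and 29 by fry in either direction. The agreement of irradiation effects between genotypes was -0.01723 without the 2 dimmest arrays.

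The genotype difference of Neil1 in sham was 1.273 and no longer called without the 2 dimmest arrays (limma adjusted p = 0.057) and in the 2-group fit (0.116). Neither of the 2 dimmest arrays is a sham array, so only the shared variance estimate and its degrees of freedom changed there. The difference ran from 1.172 to 1.392 with single arrays left out, with the call lost without wild-type sham replicates 2, 3 and 4 (1.24, 1.17 and 1.29) and labelled knockout sham replicates 1, 3 and 4 (1.20, 1.35 and 1.24). Uncalled differences of Neil1 near 0 reversed. In labelled knockout its irradiation change was -0.03836, -0.08051, -0.04614 and -0.06877 with quantile, z-score, deposited and cyclic loess values, and -0.05641 to 0.08609 with single arrays left out. Its interaction was -0.02148, -0.03648, -0.01846 and -0.01921 in the same order. With single arrays left out, the interaction ran from -0.07402 to 0.2368, the change in wild type ran from -0.2199 to 0.09098, and the average from -0.1015 to 0.05397. After irradiation the genotype difference of Aspn was 0.3842 with normexp, and that of Actb -0.003419 with quantile normalization and -0.02768 with the deposited scores.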

Other observations

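The 20 Mb test of position near Neil1 was planned, but its use against a slide difference, the test from 1 Mb, the test of probes of single genes called in sham, list tests with single arrays left out, and the test of the spread among microglia markers were chosen only after the results were seen.

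Averaged over genotypes, markers of the choroid plexus had a median change of 0.34 after irradiation, with 12 of 15 higher and 0 called by limma, also when adjusted over the list alone (camera adjusted p = 0.0011, but adjusted p = 0.334 with an estimated correlation and 0.0537 without irradiated wild-type replicate 1). Reactive astrocyte genes had a median of 0.17, with 17 of 26 higher, 0 called and 1 higher when adjusted over the list alone (camera adjusted p = 0.0107, but adjusted p = 0.248 with an estimated correlation, and 0.107, 0.0585 and 0.11 without irradiated wild-type replicate 3, labelled knockout sham replicate 3 and irradiated labelled knockout replicate 1). Neutrophil and monocyte markers had a median of 0.18, with 11 of 15 higher and 0 called either way (camera adjusted p = 0.0308, but adjusted p = 0.644 with an estimated correlation and 0.089 with the slide column as a block, and lost without any 1 of 10 arrays, up to 0.238). Among single genes, chosen after their values were seen, Fcgr4, an Fc receptor of myeloid cells, rose by 0.68 ± 0.11 (SE), and Osgin1, an oxidative stress-induced growth inhibitor, by 0.74 ± 0.10. Ly86, an accessory protein of innate immune receptors, fell by 0.52 ± 0.10, a call lost in 21 alternatives and kept in 10.

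Genotype calls in sham lay around Neil1, and 3 technical explanations were tested. A difference between slides as the whole cause is argued against by position, since 8 of 379 genes within 20 Mb were called and 0 of 17056 elsewhere (Fisher's exact p = 4.636e-14). Sequence of the donor strain kept around the targeted gene through backcrossing is a candidate explanation: with the first 1 Mb left out, 5 of 345 genes were still called against 0 of 17056 (Fisher's exact p = 2.977e-09). Variants under single probes as the whole cause are argued against for Atm and Commd4, whose other probes changed by 0.7686 and 0.9881 of the reported change (median 0.8783, lower 95% bounds 0.552 and 0.617). They stay open for the other 6 of 8 genes called in sham, among them Nrg4, at background in labelled knockout with a lower bound of 0.341, and the median of 0.6748 (-0.3264 to 0.9881) over 5 genes called near Neil1 in either comparison decides nothing, since it is the ratio of Nrg4 itself and the ratios are of changes in sham, where Dnaja4 and Mindy2 were not called; an effect of the loss of NEIL1 on its neighbours was not tested apart from these.

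Microglia markers were lower after irradiation in 18 of 24 cases, from -0.69 for P2ry12 to 0.33 for Laptm5, chosen after its value was seen. A loss of microglia would lower their markers alike if microglia alone expressed them and all probes responded alike, neither of which was tested. The SD of these changes was 0.233 against a median of 0.123 over 4900 permutations of treatment within genotypes (exact permutation p = 0.00571). The markers thus did not change alike, which argues against a loss of microglia as the sole cause only under those conditions. A mixture of fewer cells and a change within them may remain, as may a change of state alone, and neither was tested.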
